A study of Mus musculus with 9 samples.

How the data were processed

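The series held 9 polyA RNA sequencing libraries of cultured mouse cardiac fibroblasts. Per the labels' protocols, cells came from enzymatically digested hearts of adult male C57BL/6N mice. Cardiomyocytes were removed by gravity settling and the attached cells were grown on. Cultures were infected with an adenovirus carrying GFP, JP2 or shJP2 and harvested after 72 h. Stranded libraries were made with the TruSeq Stranded mRNA kit. The submitters' processing notes name DRAGEN, Salmon, DESeq2 and the mouse build GRCm39; their order, role and versions are not given in the sources used here. The values used were the deposited TPM per gene, with a deposited gene length and an effective length in bases.

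The deposited table had 56953 genes, of which 29601 were at 0 in all 9 libraries. The effective length column was found to belong to Ad-GFP replicate 3. Read depth was recovered from the steps that low values take when TPM is multiplied by effective length, so the depths are approximate. The share of low genes lying within 0.1 of a whole read was 93.3% for Ad-GFP replicate 3 and 36.8% to 63.7% for the other libraries. Floors and intervals derived from these depths cover counting error only.

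Genes with a TPM of at least 1 in at least 3 libraries were tested, 14215 in all. Values were transformed to log2(TPM + 1), a scale on which fold changes of low genes are understated. Fold ratios printed beside a log2 value are ratios of group mean TPM. One linear model with 3 group means was fitted to the 9 libraries with limma 3.58.1 in R 4.3.3, using a mean-variance trend. The 3 comparisons were two-sided moderated t-tests, and a moderated F-test asked whether the 3 groups differed at all. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 was a call. All gene-level adjusted p-values come from limma. An exact permutation test of 3 against 3 libraries has a smallest possible p of 0.1.

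Gene lists were fixed before the data were examined, as were the comparisons, the alternatives listed at the end and the rule for naming genes. Of 39 lists, 37 had at least 3 tested members and gave 111 tests over the 3 comparisons. They covered calcium (junctophilins, store-operated calcium entry, ER and plasma membrane calcium handling, calcineurin and NFAT) and matrix (collagens, other extracellular matrix and crosslinking, matrix proteases and inhibitors). Others covered activation and signalling (myofibroblast and contractile, TGF-beta signalling, YAP and SRF targets, immediate early genes, resident fibroblast identity, osteochondrogenic and adipogenic genes), angiogenic factors and angiogenesis inhibitors. Defence and growth lists were interferon response, antigen presentation, inflammatory cytokines and chemokines, complement, cell cycle and p53 targets. Stress and metabolism lists were unfolded protein response, oxidative stress response, hypoxia and glycolysis, cholesterol synthesis, oxidative phosphorylation, and lysosome and autophagy. Markers of endothelial cells, macrophages and leukocytes, cardiomyocytes, pericytes and smooth muscle, epicardium and mesothelium, Schwann and neural cells and erythroid cells were listed too. Mitochondrially encoded RNAs, ribosomal proteins, housekeeping genes and nonpolyadenylated histones served as lists of RNA content.

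Lists were tested with camera from limma, which compares the members with all other genes, at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 111 tests. The test was repeated with an estimated correlation. It was also repeated with fry, whose p asks whether the members move on balance one way and whose mixed p asks whether they move in either direction; neither compares them with other genes. Members past adjusted p 0.05 were counted after adjustment over all genes and again over the list alone.

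Genes named were the 4 junctophilins, the 8 largest rises and falls in each comparison with Ad-GFP, and 4 of each for Ad-JP2 against Ad-shJP2. These needed an adjusted p under 0.05, a mean TPM of at least 5, no overlap of the library values and a symbol that is not a numbered gene model. Up to 3 members per list and comparison with the largest change among those that passed were also named, with 6 genes called in opposite and 6 in the same direction in both comparisons with Ad-GFP. Other list members named in the text were chosen after their values were seen; these include Acta2, Tagln, Cnn1, Col1a1, Col1a2, Col3a1, Stim1, Orai1, Vegfa, Vegfd, Tgfb1, Lyz2, C1qa, Ptprc, Mrc1, Fcgr1, Hspa5, Cdk1, Mcm6, Ldha, Tcf21, Pdgfra, Tnni3, Myl2, Myh6, Tnnt2, mt-Co1, mt-Co3 and mt-Nd3. Results of 2 genes that the rule selected are not reported here; no other genes took their place, and they stayed in every test and count of genes and lists. A symbol on several lines of the table took the line with the highest mean. Reads of genes with close paralogs or pseudogenes, such as histocompatibility, heat shock and ribosomal protein genes, can be shared between them, and their values are uncertain to that extent.

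The overlap of the 2 comparisons with Ad-GFP was set against n1 x n2 / N and against 100 simulated sets of unchanged groups that share 3 controls. The shared controls could not be split. A self-test simulated Ad-JP2 against Ad-GFP on 14215 genes, 5 times, with 50 genes changed at each fold size. Recovery was 28.0% at 1.2-fold, 65.2% at 1.5-fold, 84.0% at 2-fold and 99.6% at 4-fold, with 8.2 false calls on average. Far fewer genes were changed in it than the real comparisons called. The adjustment over genes depends on that share, so recovery in the real comparisons may differ.

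The alternatives changed the pseudocount (0.1 or 5), the filter (TPM above 0 in 1 library, or at least 5 in 3), the scaling and the variance model (robust, or library weights). Scaling alternatives were median-of-ratios, quantile normalization, and TPM rescaled without Jph2, mitochondrial genes and the 50 most abundant genes. Further ones used the replicate number as a block, only the 2 groups compared, and the data without each library in turn. A correction for GC content and transcript length, and a run on protein-coding genes only, were chosen later, after the data were seen. GC content, length and biotype came from a GRCm38 reference by gene ID, while the deposited values were on GRCm39; 98.7% of the genes tested were matched. In the correction, each library's trend against GC content and length was removed before the same test, on 14025 genes.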

Results

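The data were 9 RNA sequencing libraries of primary cardiac fibroblasts from adult male mice, taken 72 h after infection with an adenovirus. There were 3 libraries each labelled Ad-GFP (control virus), Ad-JP2 (junctophilin-2 virus) and Ad-shJP2 (virus with a hairpin against junctophilin-2). Estimated depth was 40.5 to 45.7 M reads for Ad-GFP, 36.9 to 40.9 M for Ad-JP2 and 21.2 to 33.2 M for Ad-shJP2. At these depths 3 reads on 1000 bases corresponded to 0.0873 to 0.176 TPM. Between 13076 and 13931 genes reached 1 TPM in a library, and the 100 most abundant genes held 29.8% to 31.7% of the TPM. The median coefficient of variation within a group was 3.10% in Ad-GFP, 3.98% in Ad-JP2 and 3.91% in Ad-shJP2, and libraries of a group correlated at 0.985 to 0.990. The labels do not say whether replicates were separate cultures, so the p-values may measure technical spread.

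Jph2, which tethers the endoplasmic reticulum to the plasma membrane, was the only one of the 4 junctophilin genes expressed at a level that could be tested. Its TPM was 132, 127.5 and 128 in the Ad-GFP libraries, 737, 691 and 637 in Ad-JP2, and 116.5, 123 and 119 in Ad-shJP2. The group means were 129 ± 2.44, 688 ± 49.9 and 119.5 ± 3.09 TPM (SD, n = 3). The message was thus 5.32 times as high in Ad-JP2 as in Ad-GFP (log2 fold change 2.40, SE 0.05, limma adjusted p = 3.1e-08). In libraries labelled Ad-shJP2 it was 7.58% lower than in Ad-GFP (log2 fold change -0.11, SE 0.05, adjusted p = 0.072), a difference that did not pass. An exact permutation test of either comparison gave p = 0.1, its smallest possible value. After correction for GC content and length the Ad-shJP2 difference was -0.17 (adjusted p = 0.0019), and with median-of-ratios scaling it was -0.00 (adjusted p = 0.991).

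**Figure D1:**
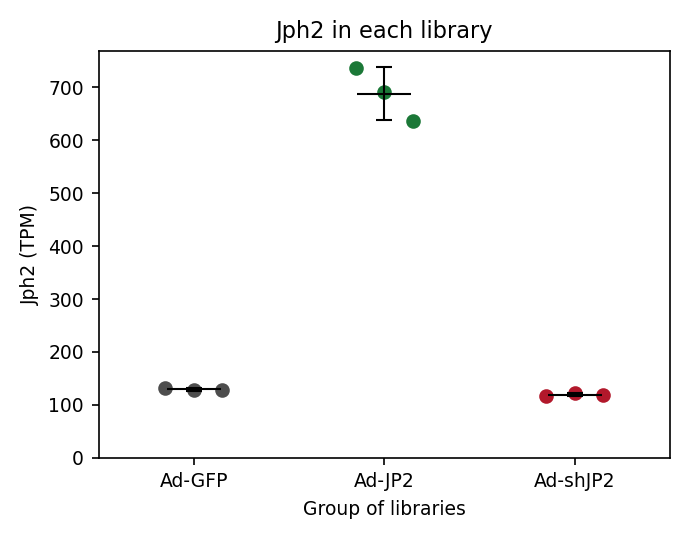
Jph2 level (TPM) in each library by group; points are libraries and bars are the mean ± SD (n = 3). Ad-JP2 stood at 688 TPM against 129 in Ad-GFP and 119.5 in Ad-shJP2.

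The first comparison asked which messages differ when Jph2 is raised. After Jph2, the largest rise in Ad-JP2 was that of the chaperone Hsp90aa1, and its ER relative Hsp90b1 rose as well. Ncl, Matr3, Zc3h15 and the importin gene Ipo7 followed. Several genes that build or crosslink matrix rose, such as Lox, Plod2 and Col8a1, while the myofibroblast actin Acta2 did not pass. Falls were fewer and small, and their number depended on the scaling (233, or 497 with median-of-ratios scaling and 748 with quantile normalization).

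Hsp90aa1 went from 36.3 ± 1.88 to 174 ± 6.45 TPM (SD, n = 3; 4.79-fold, limma adjusted p = 2.8e-06). Ipo7 rose 3.73-fold, Septin7 3.34-fold, Ncl 3.25-fold, Usp16 3.59-fold, Matr3 3.55-fold and Zc3h15 3.80-fold, and all 6 kept their calls after GC correction although these are messages of low GC content. Among the falls were the pseudogene Hmgb1-ps2 (log2 fold change -0.59), whose reads can be shared with its parent gene, and Slc35d2 (-0.47), Mcm10 (-0.45) and Hacl1 (-0.43). In all, 2135 of 14215 genes (15%) passed, 1902 higher and 233 lower, of which 300 were at least 2-fold higher and 3 at least 2-fold lower. The values of the 3 and 3 libraries did not overlap for 32.2% of genes, against 10% by chance.

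Interferon response genes were the list with the clearest movement in Ad-JP2, and all members called were higher. Over all 14215 genes 1902 were called higher and only 233 lower, so the absence of lower members says little by itself. Of 31 members 18 were higher and 0 lower (20 and 0 adjusted over the list alone), with Ifit2 (log2 fold change 1.31), Ifih1 (1.08) and Ifit1 (0.94) moving most. The list passed camera (adjusted p = 1.7e-08) and kept its call with an estimated correlation (adjusted p = 0.00903). Its median GC content was 49.9%, and 15 members stayed higher after correction, where the list's median went from 0.33 to 0.21 and Ifih1 to 0.65. Macrophage and leukocyte markers were 2 higher and 4 lower of 17 in the same libraries, with Mrc1 1.22 and Ptprc 0.94 higher (0.81 and 0.53 after correction). YAP and SRF targets had 6 of 20 higher (8 higher and 1 lower adjusted over the list alone), led by Cavin2 (1.42), Tead1 (1.06) and Crim1 (0.81). Their camera call (adjusted p = 0.0425) was lost with an estimated correlation (adjusted p = 0.281) and with median-of-ratios scaling. It was kept after GC correction (camera adjusted p = 0.00755), where 5 members stayed higher, Tead1 by 0.64 (median GC content 52.3%).

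Among calcium genes, which carry or sense calcium between stores, cytosol and outside, no member was called lower in Ad-JP2 with the main scaling. Only 233 of 14215 genes were called lower in that comparison, so a short list would hold few. Store-operated calcium entry had 5 of 16 higher, including the ER sensor Stim2 (14.3 to 24.3 TPM) and the channel Trpc1, while Stim1 (log2 fold change 0.08) and the pore gene Orai1 (-0.02) did not pass. The list was not called (adjusted p = 0.565), its median was -0.00 and its mean 0.18. ER and plasma membrane calcium handling had 7 of 18 higher, led by Atp2b1 (1.09), and was called (adjusted p = 0.0425) but not with an estimated correlation (adjusted p = 0.189). After GC correction (median GC content 53.7% and 49.5%) 2 members of each list stayed higher, and the ER list was not called (adjusted p = 0.794). Calcineurin and NFAT genes had 5 of 19 higher (6 over the list alone), with Ppp3ca (0.95) and Ppp3cb (0.70) first, and 2 higher and 2 lower after correction; the list was not called (adjusted p = 0.192). The correction brought Atp2b1 to 0.61 and Ppp3cb to 0.25.

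Most matrix and activation genes did not pass, and a few rose strongly. Collagens had 4 of 19 higher (4 higher and 1 lower over the list alone), with Col8a1 (1.38) and Col11a1 (0.84) first; Col1a1 was 0.10 higher, a call lost after GC correction and with median-of-ratios scaling. Other matrix and crosslinking genes had 3 of 25 higher, Plod2 (1.51), Lox (1.10) and Vcan (0.84), of which Vcan lost its call after correction. Myofibroblast and contractile genes had 3 higher and 2 lower of 23: Cald1 (1.49), Postn (0.81) and Actn1 (0.18) rose, while Tagln (-0.08) was among those lower and lost its call after correction, turning to 0.03 with quantile normalization. TGF-beta signalling had 5 higher and 1 lower of 24 (6 and 1 over the list alone), with Tgfbr1 (1.37) and Tgfb2 (0.68) among the rises, and matrix proteases and inhibitors 5 of 21 higher, with Adamts5 (0.90) first. None of these lists was called by camera (adjusted p = 0.143, 0.325, 0.568, 0.132 and 0.407 in the order given), while fry, which does not compare them with other genes, called all 5 (adjusted p of 2.5e-06 to 0.00518). Their median GC content ran from 49.7% to 56.4%, and after correction higher and lower members were 2 and 2, 2 and 3, 3 and 1, 3 and 4, and 4 and 1, with Col11a1 at 0.56, Tgfbr1 at 0.85 and Adamts5 at 0.36.

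In 2 lists of translation and respiration genes of the nucleus, those that passed were slightly lower. Their number depended on scaling, with 9 ribosomal and 8 oxidative phosphorylation genes lower with median-of-ratios scaling and 1 of each with quantile normalization. Ribosomal protein genes had 3 of 26 lower and 0 higher, such as Rps18 (-0.13; not called after correction), and were called (adjusted p = 3.9e-05; 0.149 with an estimated correlation). Oxidative phosphorylation had 3 of 22 lower (adjusted p = 0.000488), again not called with an estimated correlation (adjusted p = 0.0714). Oxidative stress response had 1 higher and 2 lower of 20 (adjusted p = 0.0439; 0.189 with an estimated correlation), and lysosome and autophagy 2 higher and 2 lower of 23 (adjusted p = 0.0425; 0.255 with an estimated correlation). The last list was tested as lower with a median of -0.04 but a mean of 0.01. Mitochondrially encoded RNAs had 8 of 14 higher (11 over the list alone; adjusted p = 3.8e-06, and 0.255 with an estimated correlation). Their median GC content was 36.5%, and 7 were higher and 1 lower after correction, where their median went from 0.39 to 0.17. For the 4 lists before them median GC content was 52.4%, 48.8%, 49.9% and 53%, and higher and lower members after correction were 0 and 1, 0 and 2, 0 and 4, and 1 and 3. The correction ended the ribosomal call (adjusted p = 0.176) and that of lysosome and autophagy (adjusted p = 0.105). The other 29 lists tested gave no call in this comparison (adjusted p of 0.0785 or more).

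The second comparison asked which messages differ between the hairpin virus and the GFP virus. Antiviral and interferon genes showed the largest rises, led by Cxcl10, Oasl1, Isg15 and Ccl5. Most cell cycle genes (25 of 33) and most hypoxia and glycolysis genes (15 of 23) rose with them. With an estimated correlation the interferon response and cell cycle lists kept their calls, and hypoxia and glycolysis did not. Collagens, TGF-beta signalling genes and cholesterol synthesis genes mostly fell, and so did genes of store-operated calcium entry, in a number that depended on scaling. Myofibroblast and contractile genes went both ways, 10 higher and 11 lower of 23. Acta2 and Cnn1 were among those that rose, and Cald1 and Postn among those that fell.

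Cxcl10, a chemokine, went from 0.791 ± 0.147 to 37.2 ± 1.12 TPM (SD, n = 3; 47.0-fold, limma adjusted p = 1.2e-08). The nucleic acid sensing gene Oasl1 rose 40.4-fold, Ccl5 10.9-fold, Isg15 9.42-fold, Usp18 8.90-fold, Irf7 7.97-fold, Rtp4 7.78-fold and Sprr1a 6.25-fold. The largest falls were those of Arfip1 (42.7 to 5.27 TPM, 8.10-fold lower), Il1rap (7.89-fold), Eif2s3y (7.64-fold), Dse (7.26-fold), Ccn4 (6.54-fold), Sox9 (6.49-fold), Cpd (6.08-fold) and F2r (5.76-fold). All 16 kept their calls and directions after GC correction. In all, 8446 genes (59.4%) passed, 3093 higher and 5353 lower, of which 211 were at least 2-fold higher and 936 at least 2-fold lower. The library values did not overlap for 65.3% of genes, against 10% by chance.

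Interferon and antigen presentation genes rose in Ad-shJP2, other defence genes in part. Of 31 interferon response genes 28 were higher and 1 lower, with a median log2 fold change of 1.49 (camera adjusted p = 5.4e-16; 0.00688 with an estimated correlation). The 1 that fell, Ifit2 (-0.55), lost its call after correction, where 29 were higher and 0 lower (median GC content 49.9%). Antigen presentation had 13 higher and 1 lower of 16, with H2-Q6 (1.81), H2-Q4 (1.74) and H2-Q7 (1.57) first (adjusted p = 6.8e-06; 0.0714 with an estimated correlation; median GC content 55.8%, 13 higher and 0 lower after correction). Macrophage and leukocyte markers in the same libraries had 11 higher and 3 lower of 17. Inflammatory cytokines and chemokines moved in both directions, 7 higher and 6 lower of 23: Ccl5 rose by 3.06 while Il6 fell by 2.20. Complement genes were 4 higher and 4 lower of 13, and neither of these 2 lists was called (adjusted p = 0.579 and 0.341; median GC content 49.4% and 52.3%; 10 and 5, and 5 and 2, higher and lower after correction).

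Cell cycle genes, which drive replication and division, had 25 higher and 3 lower of 33 (26 and 4 over the list alone). Ccne1 went from 22.9 to 134 TPM (5.87-fold), Cdt1 rose by 1.40 and Aurka by 1.38, while Kif23 fell by 1.37. The call (adjusted p = 2.6e-11) held with an estimated correlation (adjusted p = 0.00903), and 28 were higher and 2 lower after correction (median GC content 47.8%). Interferon response in all 3 comparisons and cell cycle in this comparison and the third were the only 5 of 41 list calls that held with an estimated correlation. Hypoxia and glycolysis genes had 15 higher and 3 lower of 23, with Slc16a3 (0.97) and Egln3 (0.82) rising, and Hif1a itself falling (-1.52, and -0.96 after correction). Their call (adjusted p = 1.8e-06; 0.189 with an estimated correlation) came with 19 higher and 3 lower after correction (median GC content 52.8%). The p53 targets had 8 higher and 6 lower of 20, 10 and 1 after correction (median GC content 49.5%), and were called only after correction (adjusted p = 0.0165, and 0.105 without it).

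Matrix genes fell in Ad-shJP2 across several families, in libraries where most macrophage and leukocyte markers rose and 7 of 9 epicardial and mesothelial markers fell. Of 19 collagens 13 were lower and 0 higher (median -0.43, adjusted p = 0.000718; 0.189 with an estimated correlation): Col8a1 fell by 1.39, Col12a1 by 1.33 and Col1a1 from 1570.3 to 964 TPM. Other matrix and crosslinking genes had 18 lower and 2 higher of 25 (median -0.35, adjusted p = 0.00168; 0.281 with an estimated correlation), with Plod2 (-2.12), Lox (-2.09) and Fbn1 (-1.03) lower. Proteases and inhibitors had 13 lower and 6 higher of 21, with Adamts5 (-2.32) and Timp3 (-2.23) lower, and were not called (adjusted p = 0.115). After correction, lower and higher members were 12 and 1, 16 and 4, and 12 and 7, the collagen median was -0.18, Col12a1 stood at -0.74 and Fbn1 at -0.60 (median GC content 56.4%, 52.5% and 49.7%).

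Most TGF-beta signalling genes, YAP and SRF targets and resident fibroblast identity genes fell in the same libraries, while myofibroblast and contractile genes were divided. TGF-beta signalling had 18 lower and 3 higher of 24, with Bmp4 (-1.66), Tgfb2 (-1.44) and Smad6 (-1.41) lower but Tgfb1 (0.61) higher (adjusted p = 0.00743; 0.286 with an estimated correlation). YAP and SRF targets had 14 lower and 2 higher of 20, with Ankrd1 (-1.90) first (adjusted p = 0.00857; 0.255 with an estimated correlation). Resident fibroblast identity genes had 17 lower and 3 higher of 24 (18 and 4 over the list alone), including Tbx20 (-1.46), Tcf21 (-1.39) and Pdgfra (-0.94) (adjusted p = 0.0109; 0.255 with an estimated correlation). After correction lower and higher members were 15 and 6, 12 and 3, and 15 and 4, with Tbx20 at -0.82 and Pdgfra at -0.47 (median GC content 52.8%, 52.3% and 52.7%). Myofibroblast and contractile genes went both ways, 10 higher and 11 lower of 23 (adjusted p = 0.755; median GC content 52.8%; 11 and 7 after correction), and their median of -0.07 turned to 0.04 with median-of-ratios scaling. Cnn1 rose by 1.01, while Postn (-1.99) and Cald1 (-1.64) fell. Acta2 was 0.30 higher (0.42 with median-of-ratios scaling and 0.34 after GC correction); quantile normalization could not test it, since it was the most abundant gene of every library.

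Calcium entry genes fell with them. Store-operated calcium entry had 11 lower and 1 higher of 16 (12 and 1 over the list alone), with Stim2 going from 14.3 to 3.93 TPM, Stim1 from 43.9 to 30.1 and Asph down by 1.22, while Orai1 (-0.10) passed only after correction (-0.17, adjusted p = 0.0038). The list was called (median -0.35, and -0.15 with quantile normalization; adjusted p = 0.0206) but not with an estimated correlation (adjusted p = 0.255) or with median-of-ratios scaling, where 7 were lower and 2 higher; 10 were lower and 1 higher after correction (median GC content 53.7%). Calcineurin and NFAT genes had 13 lower and 2 higher of 19, with Ppp3cb (-1.38) and Nfatc3 (-1.20) lower (adjusted p = 0.0416; 0.189 with an estimated correlation). After correction 9 were lower and 3 higher and the call was lost (median GC content 48.2%). ER and plasma membrane calcium handling had 11 lower and 1 higher of 18, with Canx (-1.32) first, and was not called (adjusted p = 0.112; 6 lower and 2 higher after correction, median GC content 49.5%). The correction brought Asph to -0.66, Ppp3cb to -0.83, Nfatc3 to -0.70 and Canx to -0.80, and the medians of calcineurin and NFAT genes and of ER calcium genes from -0.41 to -0.10 and from -0.31 to -0.05.

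Angiogenic factors were 12 lower and 5 higher of 24 in Ad-shJP2, where 5353 of all 14215 genes were lower and 3093 higher. The list's median went from -0.23 to -0.09 after correction. Those that fell included Slit2 (-1.31, and -0.68 after correction), Pdgfa (-1.21), Vegfa (-0.91) and Vegfd (-0.82), the last 2 named after their values were seen. Vegfa was 0.39 higher in Ad-JP2, where 4 of the 24 rose (5 over the list alone). Angiogenesis inhibitors were 9 lower and 3 higher of 14, with Timp3 and Adamts1 (-2.09) lower and Cxcl10 (4.42) higher. Neither list was called (adjusted p = 0.282 and 0.149; median GC content 50.7% and 50.8%; 9 lower and 7 higher, and 8 and 4, after correction).

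**Figure D2:**
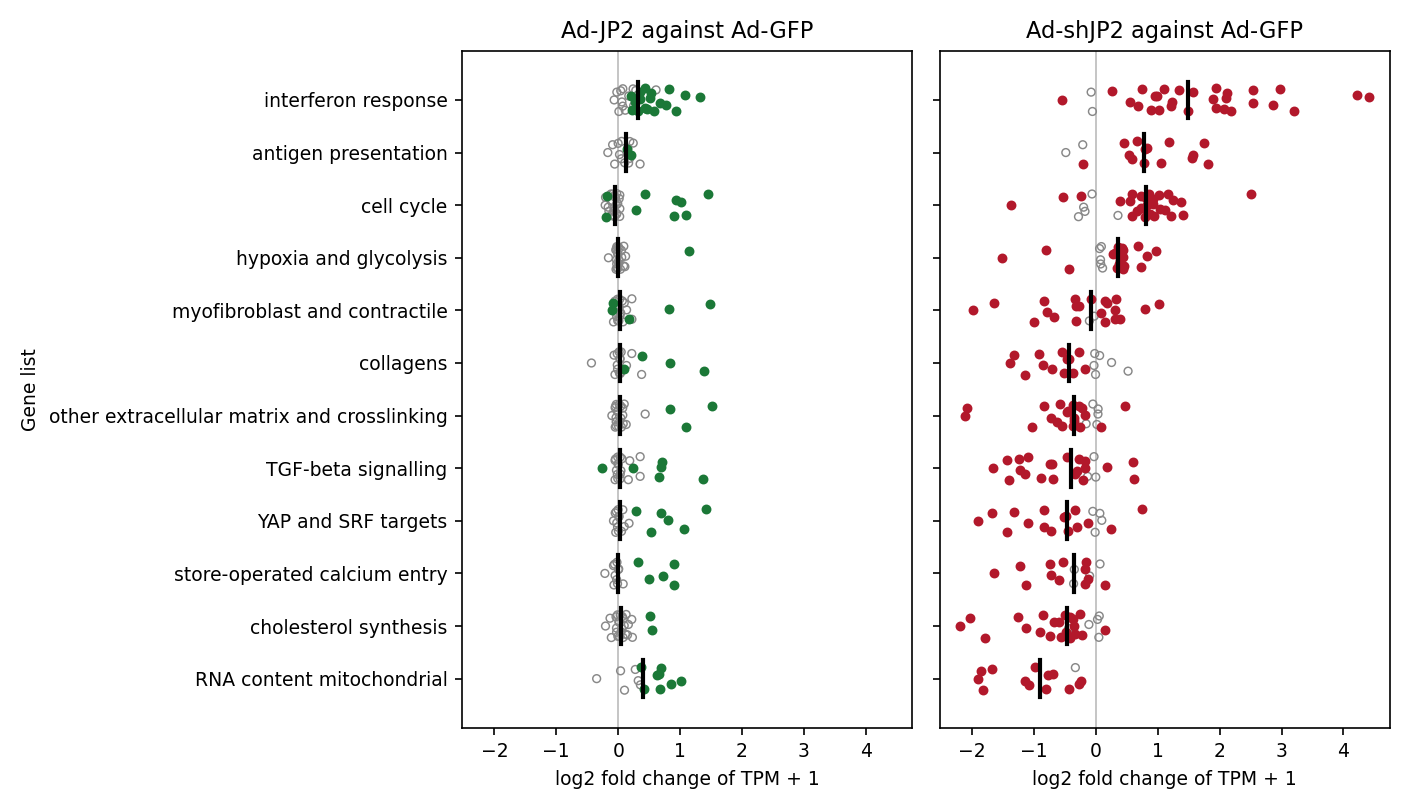
Log2 fold change of list members in Ad-JP2 and Ad-shJP2 against Ad-GFP; filled points passed adjusted p 0.05, open grey points did not, black bars are medians. Interferon response genes lay at medians of 0.33 and 1.49, collagens at 0.03 and -0.43.

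The remaining lists were small or mixed in Ad-shJP2, apart from osteochondrogenic genes, of which 5 of 6 fell (median -0.59, and -0.33 with quantile normalization). Unfolded protein response genes were 14 lower and 7 higher of 25 (14 and 8 over the list alone), with Hsp90b1 (-1.80) and Hspa5 (-1.32) lower and Atf3 (1.14) higher; immediate early genes were 9 lower and 8 higher of 19, with Klf6 (-1.86) lower and Fosl1 (1.21) higher. Ribosomal protein genes rose slightly, 16 higher and 1 lower of 26 (median 0.15; 20 higher and 0 lower with median-of-ratios scaling; adjusted p = 0.000156; 0.18 with an estimated correlation). Lysosome and autophagy genes were 6 higher and 8 lower of 23, osteochondrogenic genes 1 and 5 of 6, adipogenic genes 4 and 4 of 12 (4 and 5 over the list alone), housekeeping genes 6 and 4 of 15, and nonpolyadenylated histones 2 and 4 of 13 (1 and 4 over the list alone). With median-of-ratios scaling the balance turned for lysosome and autophagy (11 higher and 5 lower, median from -0.03 to 0.08) and immediate early genes (8 and 7), and housekeeping genes were 10 and 3; with quantile normalization histones were 2 and 0. Camera called none of these lists but the ribosomal one (adjusted p = 0.468, 0.689, 0.689, 0.107, 0.62, 0.191 and 0.978 in the order given). Higher and lower members after correction were 7 and 9, 8 and 10, 16 and 0, 9 and 7, 1 and 4, 5 and 3, 8 and 1, and 2 and 3. After correction the housekeeping list was called as higher (adjusted p = 0.0353). Median GC content was 50.6%, 54.9%, 52.4%, 53%, 49.8%, 51.8%, 49.7% and 55.1%.

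**Figure D3:**
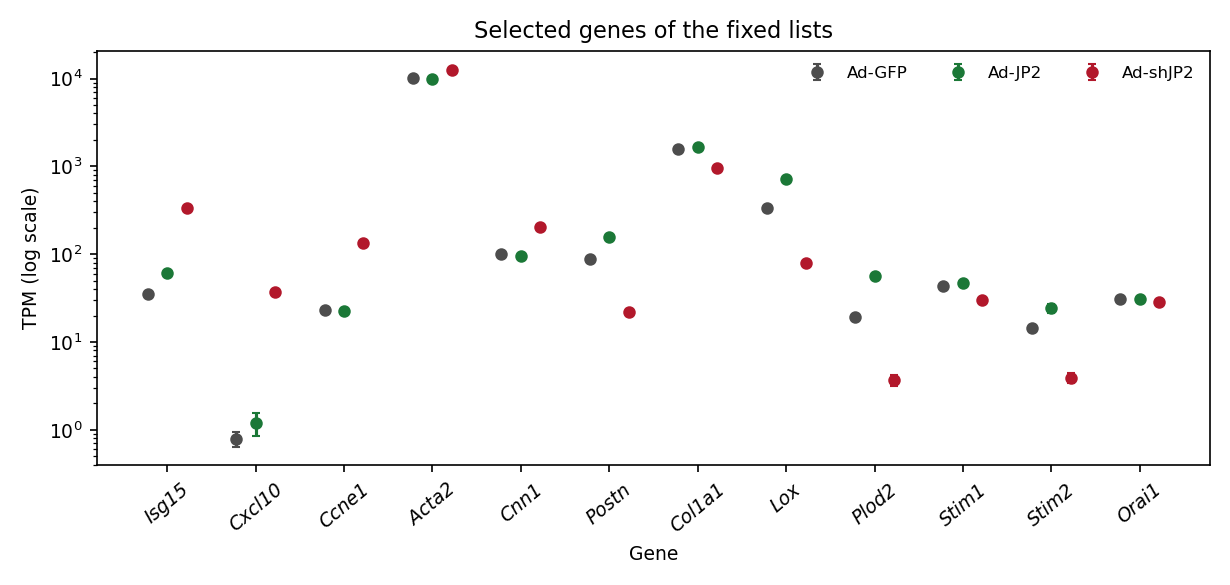
Mean ± SD TPM (n = 3, log scale) of 12 genes in the 3 groups. Isg15 and Ccne1 were highest in Ad-shJP2 (336 and 134 TPM), Lox and Plod2 highest in Ad-JP2 (722 and 56.3 TPM).

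The third comparison set Ad-JP2 directly against Ad-shJP2 and so tested whether the 2 manipulations differ. The crosslinking gene Plod2 and the chaperone gene Hsp90aa1 were far higher in Ad-JP2, and most interferon genes were higher in Ad-shJP2. Scel differed 26-fold, Plod2 15.4-fold (56.3 against 3.65 TPM), Arfip1 13.6-fold and Hsp90aa1 12.5-fold, all higher in Ad-JP2. Oasl1 was 39.1-fold, Cxcl10 31.1-fold and Ccl5 9.01-fold lower in Ad-JP2. The RNA Rn7s1 was lower too, but with 55.7 ± 54.9 TPM in Ad-shJP2 (SD, n = 3) it varied as much as it measured. Jph2 was 5.76 times as high in Ad-JP2 (log2 fold change 2.51, limma adjusted p = 8.1e-10).

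Of the calcium lists, 10 of 16 store-operated entry genes were higher in Ad-JP2 and 1 lower, with Stim2 and Asph among those higher. Calcineurin and NFAT genes were 13 higher and 1 lower of 19 (14 and 3 over the list alone). ER and plasma membrane calcium handling had 11 higher and 2 lower of 18 and was not called (adjusted p = 0.0731; 6 and 2 after correction). Collagens were 13 higher and 1 lower of 19 (14 and 1 over the list alone), other matrix genes 19 and 2 of 25, TGF-beta signalling 18 and 3 of 24, and YAP and SRF targets 14 and 2 of 20, with Tgfbr1 20.6-fold higher in TPM, from a mean of 0.354 (log2 difference 2.61), and Cavin2 9.20-fold. Interferon genes were 4 higher and 25 lower of 31, cell cycle genes 6 and 25 of 33, and hypoxia and glycolysis genes 3 and 17 of 23. Camera called these lists, the ER one apart (adjusted p = 0.0425, 0.0265, 0.000974, 0.00242, 0.00596, 0.0119, 6.2e-10, 1.7e-08 and 6e-06). With an estimated correlation the interferon and cell cycle lists kept theirs (adjusted p = 0.00903 for each), and the others did not (adjusted p = 0.281, 0.18, 0.189, 0.281, 0.281, 0.255 and 0.189). After GC correction higher and lower members were 11 and 2, 10 and 5, 11 and 3, 16 and 6, 17 and 5, 12 and 3, 3 and 27, 3 and 26, and 2 and 20, and the calcineurin and NFAT call was lost. In all, 9152 genes (64.4%) passed, 5731 higher and 3421 lower in Ad-JP2. The library values did not overlap for 67.1% of genes, against 10% by chance.

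Genes that moved in both comparisons with Ad-GFP moved mostly in opposite directions. The largest such changes were those of Acadsb, Scel, Hsp90b1, Plod2, Cald1 and Cavin2, all higher in Ad-JP2 and lower in Ad-shJP2, and all 6 kept both calls after GC correction. Plod2, an enzyme of collagen crosslinking, stood at 56.3, 19.2 and 3.65 TPM in Ad-JP2, Ad-GFP and Ad-shJP2. Genes raised by both viruses were led by interferon genes: Zbp1, Isg15, Rtp4, Parp9, Usp18 and Irf7. Isg15 stood at 61.3, 35.6 and 336 TPM in the same order.

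Counts of these genes were 1537 higher in Ad-JP2 and lower in Ad-shJP2 (716.2 from n1 x n2 / N), 97 the reverse (50.7), 82 higher in both (413.9) and 64 lower in both (87.7). Simulated unchanged groups sharing the controls gave 0 genes in opposite directions and averages of 0.02 higher and 0.01 lower in both. With no gene changed almost none is called, so these simulated counts give no size of overlap to compare with. The log2 fold changes of the 2 comparisons correlated at -0.33 with a covariance of -0.06, where shared controls alone gave 0.50 and 0.01 in the simulations. Shared controls push the 2 comparisons the same way, but before GC correction both counts in the same direction lay below n1 x n2 / N. After GC correction the counts were 556, 376, 84 and 91, and the correlation was -0.16. In that fit 864 genes were higher and 605 lower in Ad-JP2, and 4073 higher and 3704 lower in Ad-shJP2, of 14025. No n1 x n2 / N was computed for the corrected counts, so the limit to counts before correction does not mean that the shortfall ended.

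The F-test found 9061 genes (63.7%) that differed between the 3 groups. Direction depended on scaling: the median gene stood at 0.01, -0.12 and 0.10 in the 3 comparisons, and with median-of-ratios scaling at -0.01, -0.02 and -0.02. The share of calls that were higher went from 89.1%, 36.6% and 62.6% to 78.1%, 48.9% and 49.8% with that scaling, and to 66.2%, 52.4% and 42.0% with quantile normalization. Among lists that camera called, no median changed sign with either scaling. Fold changes also followed GC content, with rank correlations of -0.42 in Ad-JP2 against Ad-GFP, 0.35 in Ad-shJP2 against Ad-GFP and -0.43 in Ad-JP2 against Ad-shJP2, and transcript length at 0.40, -0.28 and 0.37. With both removed, 1469 genes passed in the first comparison (864 higher and 605 lower, 917 shared), 7777 in the second (4073 and 3704, 6335 shared) and 8562 in the third (4013 and 4549, 6594 shared).

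**Figure D4:**
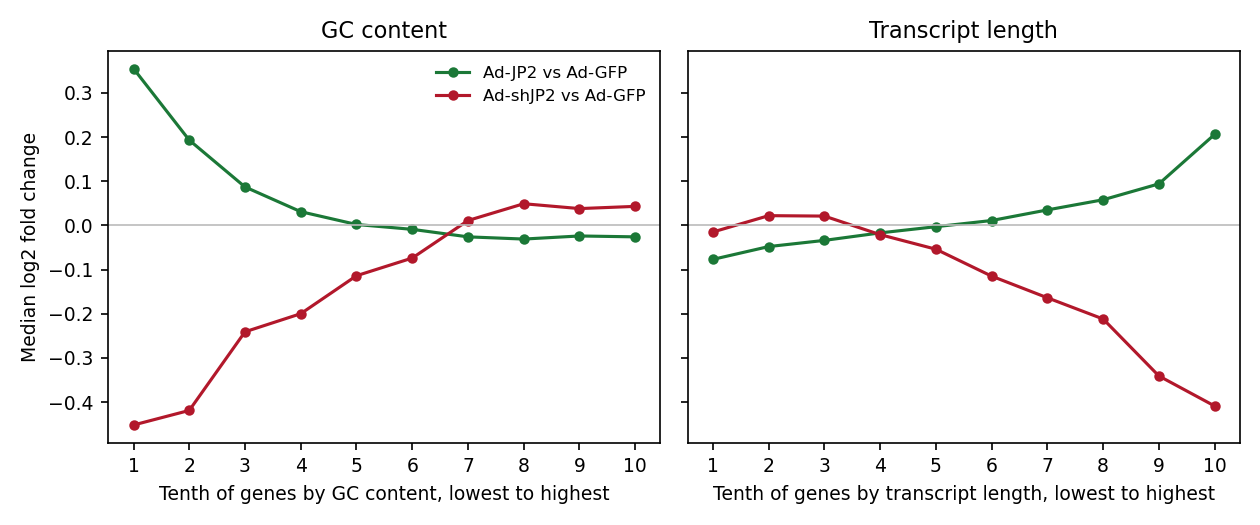
Median log2 fold change against Ad-GFP in 10 equal bins of GC content and of transcript length, for Ad-JP2 and Ad-shJP2. In the bin of lowest GC content the medians were 0.36 and -0.45, in the highest -0.03 and 0.04.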

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

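The counts of called genes stayed within 1.5 times of their value in every alternative; the largest move was that of Ad-JP2 against Ad-GFP, from 2135 to 1469 with GC and length correction. Without 1 library at a time they ran from 1648 to 2260 for Ad-JP2 against Ad-GFP, 7701 to 8502 for Ad-shJP2 against Ad-GFP, 8560 to 8993 for Ad-JP2 against Ad-shJP2 and 8401 to 8885 for any of the 3 groups. Genes moving in opposite directions ran from 1281 to 1649, and called lists from 38 to 41. The log2 fold change of Jph2 ran from 2.35 to 2.46 in Ad-JP2 against Ad-GFP, from -0.132 to -0.0949 in Ad-shJP2 against Ad-GFP and from 2.46 to 2.57 between the 2. The small Jph2 difference of Ad-shJP2 against Ad-GFP passed without Ad-JP2 replicate 1 or 3, with quantile normalization (-0.13), with only the 2 groups compared (-0.11), with library weights (-0.12) and with GC and length correction (-0.17). Genes called in opposite directions moved from 1634 to 932 with GC and length correction, with 175 in the same direction. Called lists moved from 41 to 5 of 111 with an estimated correlation and to 89 with fry, which does not compare members with other genes. A call lost with an estimated correlation need not mean correlated members. Oxidative stress response (estimated correlation -0.025) and ER and plasma membrane calcium handling (-0.013) lost calls with estimates below the preset 0.01. Others lay above it, such as TGF-beta signalling at 0.15.

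Among the named gene results, most of them picked for passing with a large change, changes of sign against a call were few. Across all genes, 917 of the 2135 calls in Ad-JP2 against Ad-GFP kept call and direction with GC and length correction. With quantile normalization Cfi went to -0.0273 in Ad-JP2 against Ad-shJP2. With GC and length correction, a sign change came for Ptgs2 (-0.00746), Lamp2 (-0.11), Slc7a11 (-0.22), Tbx20 (-0.10) and Cd36 (-0.10) in Ad-JP2 against Ad-GFP. The same correction turned Masp1 (0.0939) in Ad-shJP2 against Ad-GFP, and B2m (-0.0270) in Ad-JP2 against Ad-shJP2. Among genes named after their values were seen, it turned Ptprc (0.19) and mt-Co3 (-0.24 before correction) in Ad-shJP2 against Ad-GFP. It also turned Pdgfra (-0.06) in Ad-JP2 against Ad-GFP, and quantile normalization turned Tagln (0.03) in that comparison. The macrophage and leukocyte list in Ad-JP2 against Ad-shJP2 (median -0.19) was called in the other direction by fry (adjusted p = 0.0091). The causes were not tested.

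Over 338 named gene results, 7133 checks gave the same answer, 246 a weaker one and 8 another sign. Of the weaker ones 124 came from leaving out a library, 50 from GC and length correction, 22 from quantile normalization, 19 from dropping the filter and 11 from the replicate block. Over the 41 called lists 537 checks were the same, 77 weaker and 1 of another sign. The correction for GC and length and the run on protein-coding genes only were chosen after the data were seen; the second gave 2136, 7653 and 8161 calls.

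The replicate block changed the counts to 1929, 8226 and 9009, the F-test to 8816, opposite genes to 1485 and called lists to 38. Pairing by number had no visible basis: residual correlations of libraries with the same number ran from -0.11 to 0.11, and those of other pairs from -0.20 to 0.16. Not every library correlated best with one of its own number, so the block costs degrees of freedom for little. Depth limits low genes most in Ad-shJP2 replicate 1, at 21.2 M reads.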

Other observations

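Several movements in Ad-shJP2 against Ad-GFP concern metabolism. Cholesterol synthesis genes had 20 lower and 1 higher of 26, with Hsd17b7 (log2 fold change -2.19), Hmgcs1 (-2.03) and Scd2 (-1.79) first (camera adjusted p = 0.000549; 0.0714 with an estimated correlation; median GC content 49.6%, 20 lower and 3 higher after correction). Oxidative phosphorylation genes of the nucleus had 11 higher and 1 lower of 22, by small amounts (median 0.09; with median-of-ratios scaling 17 higher and 0 lower, median 0.20; adjusted p = 0.00492; 0.105 with an estimated correlation; 14 higher after correction). Oxidative stress response genes had 12 higher and 3 lower of 20, with Gsr (0.86) and Hmox1 (0.84) first (adjusted p = 0.00213; 0.0807 with an estimated correlation; 13 higher and 3 lower after correction). Mitochondrially encoded RNAs went the other way and unequally: 13 of 14 were lower (adjusted p = 0.00021; 0.281 with an estimated correlation), mt-Nd4l by 1.91, mt-Nd5 by 1.86 and mt-Nd4 by 1.83, but mt-Co1 by 0.44 and mt-Co3 by 0.24 (-0.05 and 0.08 after correction). In Ad-JP2 against Ad-GFP 8 rose, mt-Nd5 most (1.02, and 0.66 after correction), while mt-Co3 (0.04) did not pass, nor did mt-Nd3, which varied too much to judge (-0.35, SE 0.69). After correction 10 were lower and 1 higher in Ad-shJP2 and the median went from -0.89 to -0.43 (median GC content 36.5%).

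Markers of other heart cells were present in all groups. Macrophage genes were abundant in Ad-GFP, with Lyz2 at 1730.2 TPM and C1qa at 449.7. In Ad-shJP2 the macrophage and leukocyte list had 11 higher and 3 lower of 17, with Fcgr1 1.09 higher and Mrc1 lower (8.16 to 1.97 TPM), and was called (adjusted p = 0.0147; 0.255 with an estimated correlation). After correction 9 were higher and 2 lower and the call was lost (adjusted p = 0.0832; median GC content 51.8%). In Ad-JP2 against Ad-shJP2 this list was tested as lower with a median of -0.19 but a mean of 0.06, and its call (adjusted p = 0.0109) was lost with an estimated correlation (adjusted p = 0.255) and after correction (adjusted p = 0.131). Endothelial markers were 1 higher and 2 lower of 13 (6 and 1 with quantile normalization), cardiomyocyte markers 2 and 4 of 8, pericyte and smooth muscle markers 2 and 3 of 7, epicardial and mesothelial markers 1 and 7 of 9, and Schwann and neural markers 1 and 3 of 4. None of these 5 was called (adjusted p = 0.348, 0.937, 0.689, 0.0653 and 0.492), and no erythroid marker was expressed enough to test. The epicardial and mesothelial list (median -0.91) was called after GC and length correction (adjusted p = 0.0162). After correction higher and lower members were 4 and 0, 2 and 4, 2 and 1, 1 and 7, and 0 and 2 (median GC content 52.2%, 53.3%, 53.7%, 51.7% and 52.0%).

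The tests below were chosen after the results were seen, except those of the shallow library and of the sample splits, which were written before. Genes higher in Ad-JP2 and lower in Ad-shJP2 were rich in low GC content (median 44.2% against 50.4%) and long transcripts. With the GC and length trend removed 35.8% kept both calls, which argues against the trend as fitted being the whole cause. It does not speak to a trend that the fit removed only in part. The median rise of these genes dropped from 0.60 to 0.32 and their median fall went from -0.90 to -0.44. A fit without the shallow Ad-shJP2 replicate 1 gave 1553 such genes, 1442 of them shared with the 1537 of all libraries, which argues against that library as the cause. Whether the trend itself is technical or a real change of long messages of low GC content was not tested.

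Of the interferon response genes, 29 were higher in Ad-shJP2 with the GC and length trend removed, against 28 with it, which argues against that trend. Leukocyte markers had a median log2 fold change of 0.186 against 1.49 for the interferon list, so more leukocyte RNA would not account for the rise; a response within macrophages or fibroblasts stays open, and the direction of the leukocyte gene Ptprc is not established, at -0.36 and, after correction, 0.19 (adjusted p = 0.148). In Ad-JP2, where Jph2 was raised, 18 members were higher too. The number of groups with a control hairpin virus was 0, so an effect of the hairpin or its virus cannot be told apart from one of its target.

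Jph2 stood almost as high in Ad-shJP2 as in Ad-GFP. If cardiomyocyte RNA supplied the reads, cardiomyocyte messages would be far more abundant than Jph2. The highest of 4 markers, Tnnt2, was at 27.3 TPM in Ad-GFP and Jph2 at 129, which argues against that source. Tnnt2 stood above 1 in 10 of Jph2, the bound set for this test, so the test did not exclude the source. A second test was added after the first had missed its bound and after the 4 values were seen: the median of the markers was 0.771 TPM (Myh6 0.352, Tnni3 0.759, Myl2 0.783), which argues against it, but with less weight for having been chosen late. With the GC and length trend removed the Jph2 difference was -0.17, so the trend did not hide a large fall. Protein was not analysed here, and a lower protein level could go with a message this little changed.

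Other splits of the libraries were tried for each count. In each comparison 1 of 10 splits, the real one, reached the real number of calls (2135, 8446 and 9152), and the highest other split gave 1 call. With 10 splits no share under 0.05 is possible, so this test alone cannot tell the real groups from a chance arrangement. For the F-test over 9 libraries 1 of 100 splits reached 9061 calls, the real one, and the highest other gave 7951.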
